A study of Bos taurus with 36 samples.

How the data were processed

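The series holds 36 two-colour microarrays of cattle endometrium, the lining of the uterus, taken on day 20. On each array the RNA of 1 pregnant cow was hybridised against the RNA of 1 cyclic cow, per the labels. Of these arrays 18 carry intercaruncular tissue, the glandular lining between the caruncles, and 18 carry caruncular tissue, the aglandular knobs to which the placenta attaches. The labels give 9 pregnant and 9 cyclic animals per area, each RNA on 2 arrays, once in each channel as listed. Channel and dye are not the same in these labels, and dyes are not balanced. The pregnant RNA is in Cy5 on 3 of 10 and 5 of 8 arrays of the intercaruncular loops and on 1 of 8 and 3 of 10 arrays of the caruncular loops, and many RNAs carry the same dye on both of their arrays. The arrays form 2 closed loops per area, which run on consecutive slides and hold different animals. By label 4 pregnant and 8 cyclic animals gave both areas. Animal B4 is labelled pregnant on intercaruncular slides 64 and 65 and cyclic on caruncular slides 81 and 82.

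The authors deposited 1 table of log ratios, with 27648 spots and 36 arrays, of which 1324 values are missing. Array medians lie between -0.01 and 0.01, so the deposited log2 ratios had been centred per array. The background correction, the normalization, the base of the logarithm and the channel used as numerator are not given in the sources used here. Values are treated as log2 and no fold is printed, because only the range of the values speaks for that base. Arrays carry no sequencing depth, and the number of arrays limits the precision.

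Spots 2k-1 and 2k hold the same probe: their correlation per array is 0.72 to 0.95, against 0.04 to 0.60 for neighbouring spots of different probes. They were averaged to 13824 probes. The platform annotation given with the table names 17290 spots with 1 gene symbol and 210 with several, and does not list 10148 spots, which stay unnamed here. Of the listed spots 17240 matched a gene identifier of the RefSeq table of assembly ARS-UCD2.0, used for names and never for coordinates. Probes of one symbol were averaged, which gave 8073 named genes and 5179 single probes, 13252 features in all. Probes of one gene can disagree, as for PTGS2.

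The sign of each array was set by a rule fixed before the data were examined. Arrays that share an RNA must correlate more than arrays that do not, once all run from pregnant to cyclic. The excess correlation was 0.111 when all arrays were taken to run the same way, 0.103 when the sign followed the dye of the pregnant RNA and -0.111 when it followed channel order. The first rule was used and the second is an alternative. The excess pools the loops. Pairs sharing an RNA correlated at 0.209 to 0.771 in the loops of slides 59 to 66 and 67 to 74. Among them, pairs with the pregnant RNA in unlike dyes lay at 0.25 to 0.553, and the dye rule would turn these negative. In those loops the values argue against the dye rule. In the loop of slides 49 to 58 pairs sharing an RNA had both signs, from -0.454 to 0.456. In that of slides 75 to 84 all were negative, from -0.76 to -0.011. Other pairs of opposite channel order ranged from -0.596 to 0.531 and from -0.692 to 0.01 in these latter loops. There the rule does not settle the signs. The sign common to all arrays was set so that the median of ISG15, MX1 and MX2 is positive, because interferon tau from the embryo is textbook knowledge to induce these genes in ruminant endometrium. The direction pregnant over cyclic is therefore likely and rests on that basis, and the direction of these 3 genes is no finding. OAS1, the fourth gene of that rule, is not among the named features.

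Each area was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on features with a value on at least 12 of its 18 arrays. The effect was the intercept, with 1 term for channel order. Arrays that share an RNA had a common correlation, found by restricted maximum likelihood on a grid from 0 to 0.48 in steps of 0.02. It came to 0.02 in the intercaruncular fit and to 0 in the caruncular one. Empirical Bayes moderation was used without trend or robust options, and calls have a two-sided Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are the moderated ones. The difference between areas was fitted on all 36 arrays, and the difference between loops within each area.

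Before the data were examined, 29 gene lists were fixed. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, for lists with at least 5 measured members. Named genes followed a fixed rule. Per area it took, among genes past the threshold with the same sign in both loops, the 12 largest effects each way. Per list and area it took up to 3 members with the smallest adjusted p, and for the difference between areas the 6 largest each way. ISG15, MX1, MX2, OAS1, OXTR, ESR1, PGR, PTGS2 and IFNT were always to be given. Genes named from caruncular loop 1 alone were chosen after their values were seen, ranked by size.

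The fits were tested on simulated data of the same shape. There every array had the same noise level and the same effect, and its sign was known. Real arrays had standard deviations from 0.224 to 0.844 and some lacked the response, so the rates need not hold for them. The intercaruncular fit recovered 83.6% of features changed by 0.5 and 98.5% of those changed by 1 when arrays varied independently, at 5.1% false calls. With a share of 0.3 of the variance common to arrays of an RNA, it recovered 85.1% at 0.5, at 4.5% false calls. The caruncular fit recovered 82.1% and 85.1% at 0.5 in the same settings, at 4.1% and 7.9% false calls. One level per RNA recovered 55.2% at 0.5, 76.1% at 1 and 97% at 2 in the intercaruncular simulation with independent arrays, at 0% false calls. The fit of the difference between areas recovered 55.2% at 0.5 and 89.6% at 1.

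Alternatives fixed in advance covered the correlation of arrays, the unit of replication, the channel term, the loops, scaling, missing values, probes, thresholds, moderation, animal B4 and the sign rule. Alternatives added after seeing the data were slide 49 turned over, the second caruncular loop signed by channel order, array weights, a dye term in place of channel order (over each area and in each loop), removal of the trend along the probe order (running median over 25 probes), the fit without slides 51 and 53, loops for the gene lists, and each slide and each RNA left out in turn. Removing the arrays on which the interferon-stimulated genes did not respond was also tried while the data were explored. Its counts are not reported, because it picks arrays by the outcome. The restriction of the comparison between areas to animals found in only 1 area could not be run, because too few arrays qualify. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.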

Results

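Gene expression in cattle endometrium was compared between pregnancy and the cycle on day 20 in 2 areas of the uterus. The data are log ratios from 36 two-colour arrays, 18 of intercaruncular and 18 of caruncular tissue, with 9 pregnant and 9 cyclic animals in each area. Effects are mean log ratios, treated as log2, in the likely direction pregnant over cyclic. That direction rests on interferon-stimulated genes being positive, so their sign is no finding. The arrays form 2 loops per area: slides 49 to 58 and 59 to 66 for intercaruncular tissue, slides 67 to 74 and 75 to 84 for caruncular tissue.

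The arrays did not all behave alike. ISG15, a ubiquitin-like protein induced by interferon, had a log ratio of 3.01 to 6.42 on 12 of the 18 intercaruncular arrays, and of 3.92 to 6.42 on all 8 arrays of caruncular loop 1. On intercaruncular slide 49 it was -3.36, and that array correlated at r = -0.51 across features with the mean of the other arrays of its area. It was between -0.49 and 0.23 on slides 51, 53, 54, 64 and 65. Slides 53 and 54 carry animal B98070 and slides 64 and 65 carry animal B4, both labelled pregnant. On the 10 arrays of caruncular loop 2 ISG15 lay between -0.27 and 0.50. The direction of slide 49 is not settled, because it ran against the mean of its area. That of caruncular loop 2 is not settled, because 20 of its 25 pairs of opposite channel order correlated below -0.3. Counts with these signs turned are given below.

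**Figure D1:**
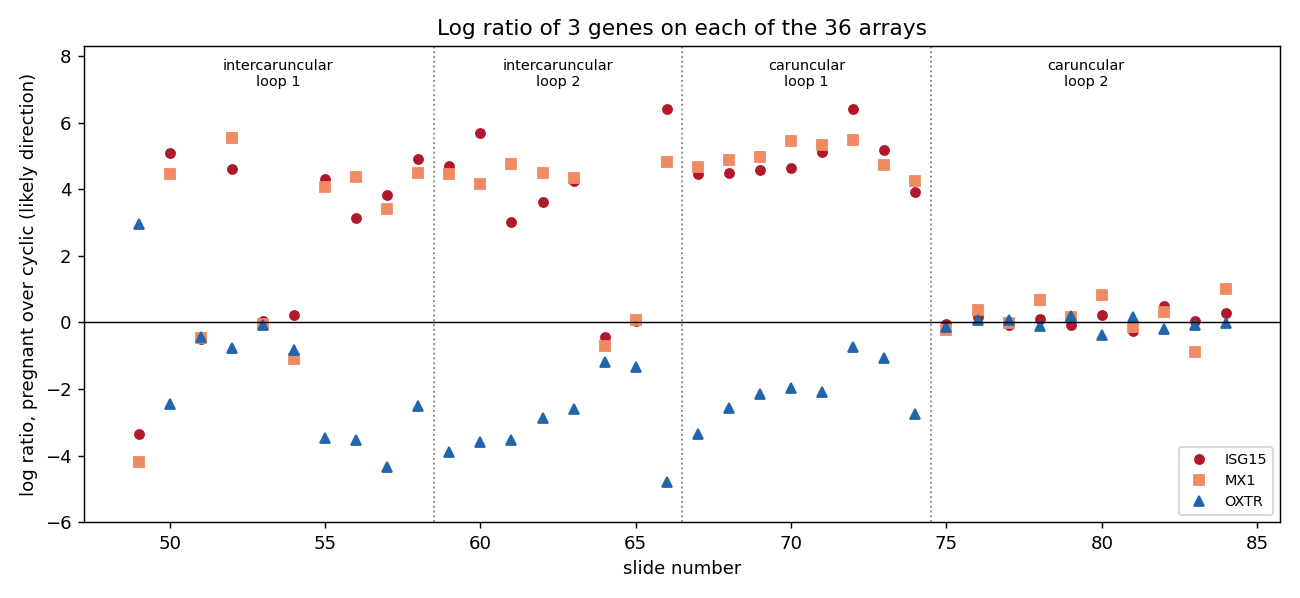
Log ratio of ISG15, MX1 and OXTR (vertical axis, pregnant over cyclic in the likely direction) on each array, ordered by slide number, with dotted lines between the 4 loops. Each point is 1 array; slide 49 has ISG15 at -3.36, and the 10 arrays of caruncular loop 2 stay between -0.27 and 0.50.

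In intercaruncular tissue 25 of 27 interferon-stimulated genes, 8 of 14 genes of MHC class I and 8 of 18 complement genes were higher in pregnancy, and 14 of 36 extracellular matrix genes (2 were higher) and 6 of 15 smooth muscle genes were lower. These lists passed with a preset correlation and not with an estimated one (adjusted p = 0.166 with an estimated correlation for the first 3, 0.472 for matrix and 0.241 for smooth muscle). RSAD2, an antiviral enzyme induced by interferon, had the largest effect, 3.27 (SE 0.72, n = 18 arrays, adjusted p = 0.00773 by limma, above 0 on 14 arrays). ISG15 had 2.76 (SE 0.61), MX1 2.61 (SE 0.61) and MX2 2.13 (SE 0.48), the latter pair being antiviral GTPases. OXTR, the oxytocin receptor through which oxytocin drives luteolytic prostaglandin release, had -2.18 (SE 0.43, adjusted p = 0.00465) and was below 0 on 17 of 18 arrays. In all, 770 features were higher and 682 lower among 13246 tested. The p values count 18 arrays, though each RNA is on 2 of them. They use 1 common correlation of 0.02 between arrays of an RNA, while both arrays of B98070 and of B4 lacked the interferon response. With one level per RNA limma called 0 features (899 at an unadjusted p under 0.05). In simulated intercaruncular data that fit made 0 to 0.6% false calls, against 4.5 to 5.1% for the main fit. It is the stricter fit, so its count of 0 does not show that an effect is absent. Leaving out single slides or RNAs in the main fit gave as few as 556.

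Other genes with large positive effects were the ferritin receptor SCARA5 (2.12, SE 0.36), the WNT antagonist DKK1 (1.92, SE 0.44), the oxysterol hydroxylase CYP39A1 (1.88, SE 0.33) and HPGD, which inactivates prostaglandins (1.85, SE 0.48). LOC282255 had 1.76 (SE 0.35), the fatty acid binding protein FABP3 1.73 (SE 0.45), and the complement protease C1R and the helicase-like ZNFX1 1.71 each (SE 0.30 and 0.39). The largest negative effects after OXTR belonged to the collagen chain COL1A2 (-1.95, SE 0.38) and the matrix glycoprotein SPARC (-1.87, SE 0.36). GADD45G had -1.67 (SE 0.30), CCN3 -1.65 (SE 0.29), the smooth muscle actin ACTG2 -1.58 (SE 0.27) and the neuropeptide NPY -1.56 (SE 0.45). SNAI2, a repressor of epithelial genes, had -1.55 (SE 0.30), PMEPA1 -1.48 (SE 0.31), COL1A1 -1.44 (SE 0.43), PRXL2A -1.44 (SE 0.35) and MFAP5 -1.39 (SE 0.27). Their adjusted p values by limma were at most 0.0364.

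Of 27 interferon-stimulated genes, 25 were higher over all genes tested and 26 adjusted over the list alone, with a median of 1.29. EPSTI1 had 1.67 (SE 0.31), PARP9 1.42 (SE 0.28) and the transcription factor IRF1 0.73 (SE 0.14). Of 14 genes of MHC class I and peptide loading, 8 were higher, and 10 adjusted over the list alone. The immunoproteasome subunit PSMB9 had 1.02 (SE 0.21) and BOLA-NC1 0.84 (SE 0.15). Of 9 MHC class II genes 4 were higher, and 5 adjusted over the list alone, led by BOLA-DRA at 0.83 (SE 0.13). Of 18 complement genes 8 were higher, and 10 adjusted over the list alone, among them C1S at 1.42 (SE 0.26) and C4A at 0.72 (SE 0.14). Of 19 T and NK cell markers only NKG7 passed, at 0.27 (SE 0.08), and none adjusted over the list alone.

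Of 36 extracellular matrix genes 14 were lower and 2 higher, and 16 lower and 2 higher adjusted over the list alone. COL12A1 had -1.30 (SE 0.23) and FBLN5, an elastic fibre protein, -0.66 (SE 0.12). Of 15 smooth muscle markers 6 were lower, and 7 adjusted over the list alone, including TAGLN at -1.29 (SE 0.28) and TPM1 at -0.60 (SE 0.13). Of 16 stromal markers 5 were lower and 1 higher, NR2F2 at 0.70 (SE 0.15), and 7 and 1 adjusted over the list alone. Of 22 endoplasmic reticulum chaperones and unfolded protein response genes 8 were lower, and 12 lower and 2 higher adjusted over the list alone. SEC61B, a subunit of the protein translocation channel, had -0.67 (SE 0.10), and the folding factors DNAJB11 and PDIA6 had -0.61 (SE 0.12) and -0.59 (SE 0.12). Of 41 cell cycle genes 5 were lower and 2 higher, and 6 and 2 adjusted over the list alone. PCNA, the replication clamp, had -0.41 (SE 0.08), while cyclin CCND3 had 0.96 (SE 0.18). Of 54 oxidative phosphorylation genes 4 were lower and 1 higher, and as many adjusted over the list alone, with NDUFB5 at -0.55 (SE 0.08) and ATP5PF at -0.51 (SE 0.08).

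These 11 lists passed camera with the preset correlation. Adjusted p ranged from 5.10e-21 for interferon-stimulated genes to 0.0363 for T and NK cell markers and for oxidative phosphorylation. None passed with an estimated correlation, where adjusted p was 0.166 for the interferon, MHC class I, MHC class II, complement and T and NK lists. It was 0.215 for chaperones, 0.241 for smooth muscle, 0.472 for extracellular matrix, 0.507 for stromal markers and cell cycle, and 0.672 for oxidative phosphorylation. By fry, which tests members without comparing them with other genes, 9 lists passed. They were these lists other than stromal markers (adjusted p = 0.126), cell cycle (0.123), extracellular matrix (0.0783) and oxidative phosphorylation (0.333), together with prostaglandin genes (0.0221) and solute transporters (0.0494), which did not pass camera. The oxidative phosphorylation list turned direction in loop 1, where it did not pass (adjusted p = 0.179).

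By limma, loop 2 alone called 2121 features and loop 1 alone 0 (1010 at an unadjusted p under 0.05). With the loop as a block, a fit that gives each loop its own effect and tests their mean, 1948 were called. Leaving out each slide or RNA in turn gave between 556 and 2040. The count was 1709 with slide 49 turned, and 0 both with one level per RNA (899 at an unadjusted p under 0.05) and with signs by dye (194 at an unadjusted p under 0.05). Within loop 2 the correlations of arrays that share an RNA argue against signs by dye.

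In caruncular tissue the fit over all 18 arrays called 4 features, all lower in pregnancy. They were COL1A2 (-1.30, SE 0.20, adjusted p = 0.0326, below 0 on all 18 arrays), SPARC (-1.05, SE 0.18, adjusted p = 0.0463), the ribosomal protein RPS2 (-0.54, SE 0.09, adjusted p = 0.0463) and MYBPH (-0.42, SE 0.07, adjusted p = 0.0486). ISG15 had a mean of 2.20 (SE 0.56) and MX1 2.32 (SE 0.55), both with adjusted p = 0.0771, and 2318 features had an unadjusted p under 0.05. The loops differed: loop 1 alone called 603 features higher and 438 lower, and loop 2 alone called 0, with 567 at an unadjusted p under 0.05. With the loop as a block limma called 854 higher and 689 lower. That fit tests the mean of the 2 loop effects, so its calls can rest on loop 1 alone. RSAD2, for one, had 2.93 (SE 0.09) in it, from 5.69 in loop 1 and 0.17 in loop 2. The count was 0 without the arrays of animal B4 (2275 at an unadjusted p under 0.05), without the channel term (2251), with one level per RNA (861) and with a dye term in place of channel order (1476), an alternative added after the data were seen. With loop 2 signed by channel order 341 features were called, and 922 with that sign turned.

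In caruncular loop 1, on 8 arrays of 4 pregnant and 4 cyclic animals, the genes with the largest effects were chosen after their values were seen. RSAD2 had 5.69 (SE 0.20), FABP3 5.22 (SE 0.34), MX1 4.96 (SE 0.15), ISG15 4.85 (SE 0.27) and MX2 4.16 (SE 0.29). DKK1 had 4.02 (SE 0.23), PLET1 4.00 (SE 0.36), the carbonic anhydrase CA2 3.60 (SE 0.36) and SCARA5 3.59 (SE 0.32). PLAC8B, LOC282255 and MS4A8 followed with 3.27 (SE 0.25), 3.21 (SE 0.17) and 3.15 (SE 0.35). NPY was lowest at -3.58 (SE 0.15), followed by the kinase PLK2 at -2.46 (SE 0.28) and the matrix protein tenascin, TNC, at -2.40 (SE 0.19). RARRES1 had -2.37 (SE 0.18), ATP13A1 -2.20 (SE 0.56), COL12A1 -2.19 (SE 0.26), GADD45G -2.19 (SE 0.52), CCN3 -2.18 (SE 0.39) and OXTR -2.09 (SE 0.30). COL1A2 and ANGPTL2 had -1.89 each (SE 0.20 and 0.23) and TAGLN -1.88 (SE 0.31). All had adjusted p values by limma of up to 0.0483 in that loop. The pregnant RNA was in Cy3 on 7 of these 8 arrays, so dye and pregnancy are poorly separated. With a dye term in place of channel order 417 features were called in that loop (300 higher, 117 lower), among them all of these genes except ATP13A1, GADD45G and TAGLN. The collagen genes COL3A1 and COL1A1 did not pass that fit either. In loop 2 OXTR had -0.04, NPY -0.04 and RSAD2 0.17, while COL1A2 had -0.83 (SE 0.22), SPARC -0.57 (SE 0.16), COL3A1 -0.55 (SE 0.14) and COL1A1 -0.39 (SE 0.06), none past the threshold.

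Over all 18 caruncular arrays 8 lists passed camera with the preset correlation. Interferon-stimulated genes (27 members, median 0.84), MHC class I (14 members, 0.34), oxidative phosphorylation (54 members, 0.14) and trophoblast markers (18 members, 0.12) lay on the higher side. Extracellular matrix (36 members, -0.24), stromal markers (16 members, -0.41), smooth muscle (15 members, -0.21) and cytosolic ribosomal proteins (55 members, -0.21) lay on the lower side. Over all genes tested only 2 matrix genes, COL1A2 and SPARC, the stromal list's COL1A2 and the ribosomal RPS2 passed. Adjusted over the list alone, 24 interferon, 10 MHC class I and 10 oxidative phosphorylation genes were higher, and 22 matrix, 10 stromal, 5 smooth muscle and 26 ribosomal genes were lower, with 1 matrix and 1 stromal gene higher and no trophoblast gene past the threshold. With an estimated correlation none passed, with adjusted p = 0.186 for the interferon, MHC class I, smooth muscle, stromal, matrix and ribosomal lists and 0.437 for trophoblast markers and oxidative phosphorylation. By fry 6 passed, with adjusted p from 0.00841 for stromal markers to 0.0301 for MHC class I, and trophoblast markers (0.129) and oxidative phosphorylation (0.152) did not. Trophoblast markers and oxidative phosphorylation turned direction in loop 2 alone, where neither passed camera (adjusted p = 0.704 and 0.268). With the loop as a block, a setting added for lists after seeing the data, the estimated correlation gave adjusted p = 0.000669 for interferon-stimulated genes, 0.00409 for MHC class I and 0.00696 for smooth muscle and for matrix. These values, too, are for the mean of the loop effects and can rest on loop 1 alone.

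Genes of these lists in caruncular tissue had values that did not pass over 18 arrays. B2M, the light chain of MHC class I, had 1.31 (SE 0.30, adjusted p = 0.0771) overall and 2.75 (SE 0.12) in loop 1, where it passed (adjusted p = 2.68e-05). COL3A1 had -1.12 (SE 0.20, adjusted p = 0.0559), and CNN1, a smooth muscle calponin, -0.75 (SE 0.19, adjusted p = 0.0771). ATP5MC3, a subunit of ATP synthase, had 0.50 (SE 0.13, adjusted p = 0.078). PAG17, a pregnancy-associated glycoprotein of the trophoblast, had 0.44 (SE 0.14, adjusted p = 0.0988), and IFNT2, an interferon tau gene, 0.26 (SE 0.10, adjusted p = 0.162).

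Of the receptors fixed in advance, PGR, the progesterone receptor, was lower in intercaruncular tissue at -0.44 (SE 0.11, adjusted p = 0.0181) and had -0.33 (SE 0.12, adjusted p = 0.161) in caruncular tissue. ESR1, the oestrogen receptor, had -0.26 (SE 0.09, adjusted p = 0.0792) and -0.08 (SE 0.09, adjusted p = 0.734). OXTR had -0.95 (SE 0.27, adjusted p = 0.0795) in caruncular tissue. PTGS2, the inducible cyclooxygenase, had 0.35 (SE 0.15, adjusted p = 0.139) and 0.44 (SE 0.13, adjusted p = 0.0882), averaged from 2 probes that disagreed. One probe had 0.08 and the other 0.62 in intercaruncular tissue, and 0.09 and 0.80 in caruncular tissue. OAS1 and IFNT are not among the named features.

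The effect of pregnancy differed between areas for 50 features, 25 with a higher and 25 with a lower value in caruncular tissue. SLC16A11, a monocarboxylate transporter family member, differed most, by -1.37 (SE 0.28, adjusted p = 0.0319), with 1.63 in intercaruncular and 0.25 in caruncular tissue. PPDPF differed by -0.81 (SE 0.18), DBP, a circadian transcription factor, by -0.81 (SE 0.18), CTSF, a lysosomal protease, by -0.79 (SE 0.16), NOP53 by -0.69 (SE 0.14) and BOLA-DRB3 by -0.60 (SE 0.15). In the other direction stood P2RY14 (0.75, SE 0.17), COX7A2, a subunit of cytochrome oxidase (0.74, SE 0.17), DNAJB11 (0.60, SE 0.14), TMEM165 (0.59, SE 0.11), the mitochondrial pyruvate carrier MPC2 (0.59, SE 0.10) and PDIA5 (0.58, SE 0.12). The 10 arrays of caruncular loop 2 showed almost no interferon response, so a difference between areas over all arrays cannot be told apart from that loop. In loop 1 alone the difference was 0.195 for P2RY14, 0.24 for DNAJB11, 0.131 for PDIA5 and -0.5 for SLC16A11. For COX7A2 (0.897) and NOP53 (-0.987) it was larger there than over all arrays. Limma called 0 differences in loop 1 alone (908 at an unadjusted p under 0.05) and 2301 in loop 2 alone. It called 0 without animal B4 (1158 at an unadjusted p under 0.05) and with one level per RNA (239), 4 with arrays scaled and 153 with slide 49 turned.

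By list, the difference passed camera for 9 lists with the preset correlation and for none with an estimated one, where their adjusted p lay between 0.371 and 0.716. Fry called none. Oxidative phosphorylation (median difference 0.20, 3 members past the threshold) and chaperones (0.30, 1 member) lay on the side of caruncular tissue, as did cell cycle (0.09, 2 members) and glycolysis genes (0.17, none). Cytosolic ribosomal proteins (-0.17, 1 member), interferon-stimulated genes (-0.26, none), endothelial markers (-0.14, none), complement (-0.17, 1 member) and MHC class II (-0.10, 1 member) lay on the other side. Adjusted over the list alone, 17 oxidative phosphorylation genes, 5 cell cycle genes, 4 chaperones, 3 ribosomal genes, 2 MHC class II genes, 1 complement gene and 1 glycolysis gene passed. In loop 1 alone the interferon list lay the other way, with a median difference of 1.04 (adjusted p = 1.66e-12). MHC class II and complement also lay the other way there, without passing (adjusted p = 0.784 and 0.179). Intercaruncular loop 1 holds slide 49, of opposite sign, and slides 51, 53 and 54, without an interferon response. Their interferon list medians were -1.20, -0.25, 0.03 and -0.06. The other arrays of that loop lay at 1.23 to 2.30, against 1.5 to 2.66 in caruncular loop 1. The difference in loop 1 therefore cannot be told apart from these slides.

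Across 13023 features with a value on all arrays, the effects in the 2 areas correlated at r = 0.67 (Spearman 0.43). Genes are not independent replicates, and 12 animals are in both areas with the same label. Animal B4 is also in both, with opposite labels, which the splits below do not reproduce because they give each animal 1 label. In 100 splits of the animals, each keeping its label in both areas, r ranged from -0.41 to 0.69 with a median of 0.08, and 1 of the splits reached the observed value. The covariance was 0.0272 against a mean of 0.0039 over the splits. Within loop 1 r was 0.69, where 5 splits were as large, and within loop 2 it was 0.08, where 13 splits were as large. Between the intercaruncular calls and those of caruncular loop 1, 274 features were higher in both, 170 lower in both and 5 called in opposite directions. Some animals are in both sets, so a count expected for independent lists does not apply. The effects of these 2 fits correlated at r = 0.70, against a median of 0.14 and a highest value of 0.74 in 100 splits of the animals, of which 4 were as large.

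**Figure D2:**
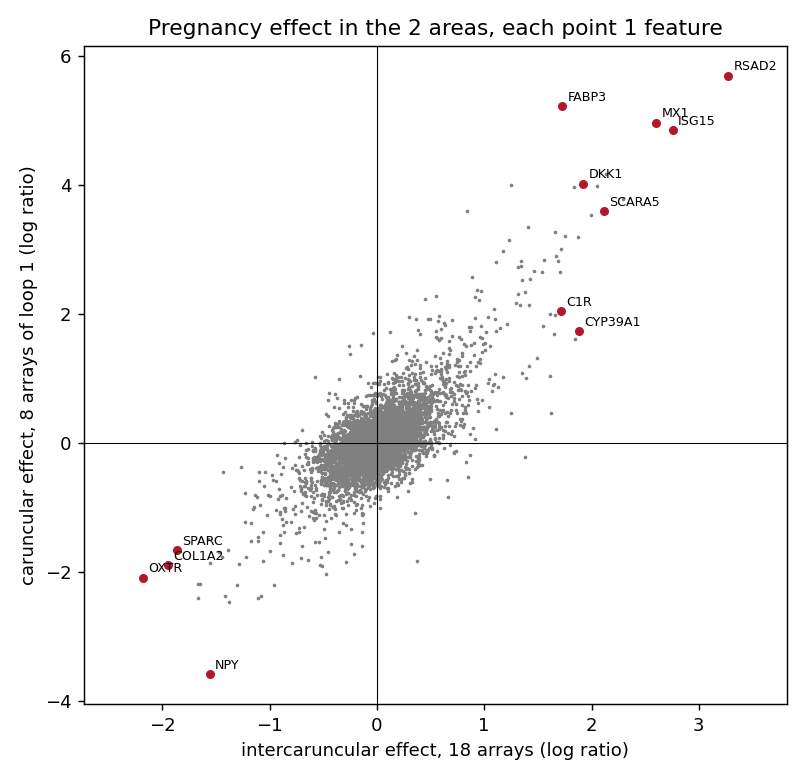
Effect of pregnancy in intercaruncular tissue (horizontal axis, mean log ratio over 18 arrays) against caruncular loop 1 (vertical axis, 8 arrays), 1 point per feature, with 12 genes named. RSAD2 lies at 3.27 and 5.69, and NPY at -1.56 and -3.58.

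Within areas the loops were compared directly. In intercaruncular tissue the effects of the loops correlated at r = 0.65 across features (Spearman 0.46), and 48 features differed between them. In caruncular tissue r was 0.12 (Spearman 0.11), 1356 features differed, and the slope of loop 2 on loop 1 effects was 0.03. Of the 1041 features called in caruncular loop 1, 638 had the same sign in loop 2.

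**Figure D3:**
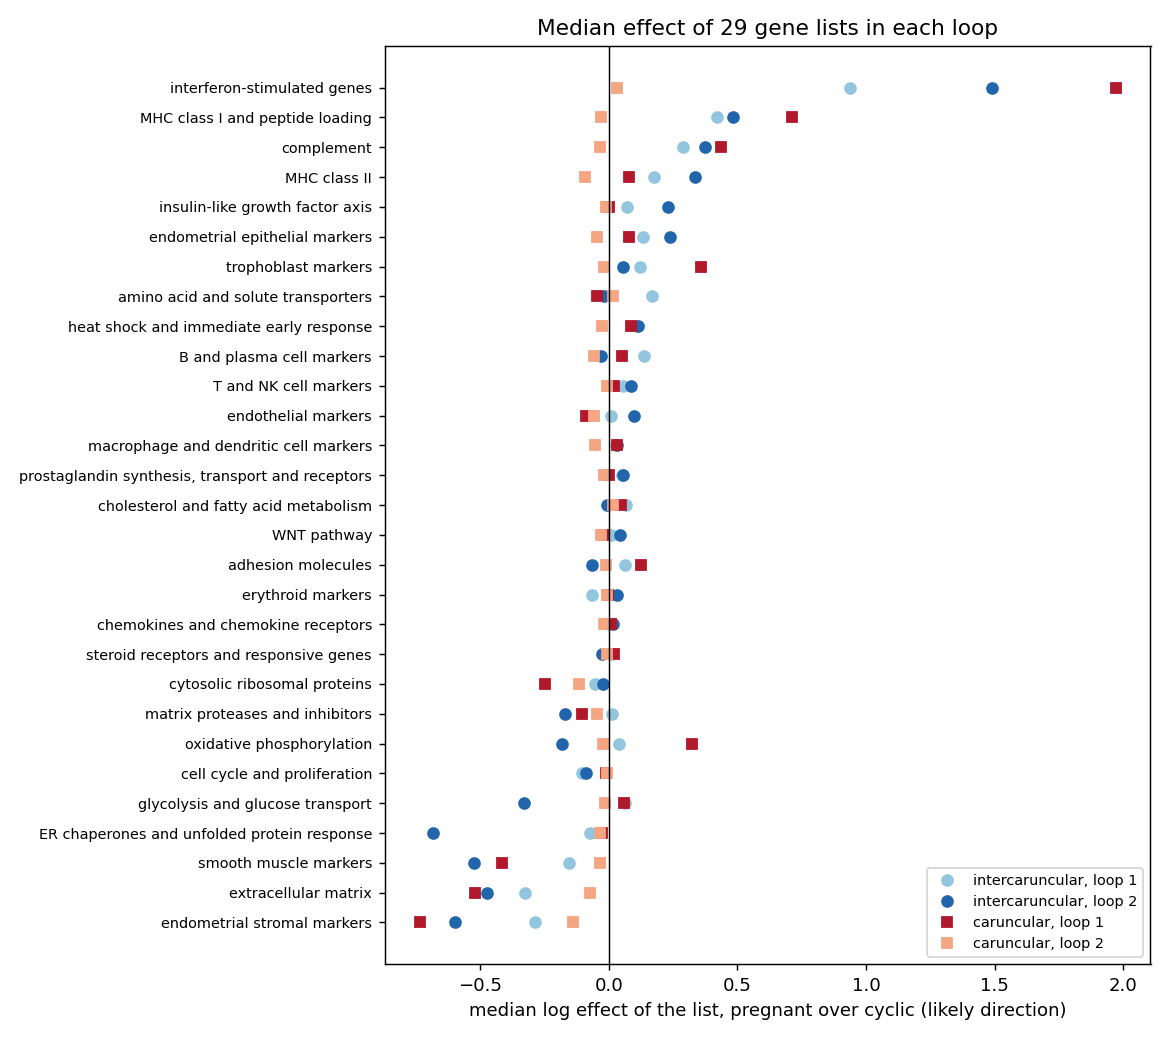
Median effect of each of the 29 gene lists (horizontal axis, log ratio in the likely direction pregnant over cyclic), 1 row per list and 1 point per loop. For interferon-stimulated genes caruncular loop 1 lies at 1.97, and points of caruncular loop 2 lie near 0 in most lists.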

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

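The tests of technical explanations for the 3 patterns described last were chosen after the results were seen. The comparisons with other splits of the samples were planned.

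The effect of pregnancy differed between the areas for 50 features by the test of the difference itself. For the genes taken by the fixed rule, caruncular minus intercaruncular values were 0.748 for P2RY14, 0.735 for COX7A2, 0.603 for DNAJB11, 0.594 for TMEM165, 0.585 for MPC2 and 0.584 for PDIA5. They were -1.373 for SLC16A11, -0.810 for PPDPF, -0.808 for DBP, -0.787 for CTSF, -0.688 for NOP53 and -0.604 for BOLA-DRB3. In 100 splits of the arrays into areas the highest other count was 17, so chance division of single arrays can be excluded (1 split as large, the real one). These splits do not keep the arrays of an RNA or an animal together. The fit with one level per RNA and the animal as a random block, which does, called 0 by limma (239 at an unadjusted p under 0.05). None of the 12 genes passed in loop 1 alone or without animal B4.

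Among gene lists 9 differed between areas by camera with the preset correlation. None did with an estimated correlation (their adjusted p = 0.371 to 0.716 with an estimated correlation) or by fry, and in loop 1 alone the lists of interferon-stimulated genes (adjusted p = 1.66e-12), MHC class II (0.784) and complement (0.179) lay the other way. Intercaruncular loop 1 holds slide 49, of opposite sign, and slides 51, 53 and 54, without an interferon response. With the preset correlation adjusted p was 0.0291 for interferon-stimulated genes, 0.0269 for MHC class II and for complement, 0.0324 for endothelial markers, 0.000271 for cell cycle, 0.0199 for glycolysis, 5.73e-11 for oxidative phosphorylation, 1.61e-05 for cytosolic ribosomal proteins and 1.04e-06 for endoplasmic reticulum chaperones. Of 100 splits 12 gave as many lists, the highest other giving 11, so chance cannot be excluded for that count.

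The loops differed for 48 features in intercaruncular tissue. Of 100 splits 2 gave as many, and the highest other gave 78, above the real count, so chance cannot be firmly excluded. In caruncular tissue the loops differed for 1356 features, where 1 of 100 splits, the real one, gave as many and the highest other gave 296. These splits, too, were of single arrays and do not keep the arrays of an RNA together.

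For the counts of the report, splits exchanged the status of whole RNAs within loops, so that both arrays of an RNA stayed together. The intercaruncular 1452 stood against 12 in the highest of the other splits (1 of 100 splits as large). Splits of this kind cannot exclude chance in either area, because only the real one gives every array a contrast. In the others, arrays whose RNAs get the same status carry none, and the real effect adds to the error. They therefore tend to call fewer features from the outset. The intercaruncular fit with one level per RNA called 0 by limma (899 at an unadjusted p under 0.05). The intercaruncular 11 lists stood against 13, with 11 of 100 splits as large, and chance cannot be excluded. The 4 caruncular features stood against 1802, with 5 of 100 splits as large. Chance cannot be excluded there, and a split with that many calls points to a structure of the samples. The 8 caruncular lists stood against 13, with 56 of 100 splits as large. In caruncular loop 1 the 1041 features stood against 1 in 35 splits, and with the loop as a block 1543 stood against 1034, each with 1 split as large, the real one. In the blocked fit 47 of the other splits called at least 1 feature.

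The first pattern weighed is the weak response on the 10 arrays of caruncular loop 2, whose interferon list medians lay between -0.03 and 0.05, against 1.5 to 2.66 in loop 1. A complete loss of probe order is excluded, because the loop means correlated at 0.129 at matched positions and at most at 0.041 over 1000 shifts. That test cannot exclude that part of the probes are out of order. With the trend along the probe order removed, the slope of loop 2 on loop 1 effects was 0.030, against 0.031 with it. That test cannot exclude a fault tied to position, because taking off an additive trend could not restore effects that were lost. Neighbouring probes correlated at 0.191 to 0.621 on the loop 2 arrays, against 0.037 to 0.274 in loop 1. Animals B2 and B3 responded in intercaruncular tissue, where their arrays had medians of at least 1.928. Those are separate extracts, so they cannot exclude that the caruncular RNA labelled B2 or B3 carries no response. By label, slides 76 and 77 hold the same animal pairs as intercaruncular slides 59 and 66, with medians of 0.015 and -0.024 against 1.986 and 2.7. For those animals the values argue against a lack of response, if the labels hold and both areas respond. A fault in hybridisation or labelling remains open, as does a difference between the other animals on their own arrays. Probes of one gene correlated at -0.080 to 0.186 on the loop 2 arrays against 0.243 to 0.429 in loop 1. However, intercaruncular slides without an interferon response had both high values (0.274 to 0.320 on 54, 64 and 65) and low ones (0.053 on 51, 0.178 on 53).

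The opposite sign of slide 49 is the second pattern. A ratio turned over as a whole cannot be told apart from other causes, because the slope of the array on the mean of the others, -0.612, restates the opposite sign. Wrong RNA of the same kind in both channels is excluded, because it needs a slope near 0 and the correlation was -0.510. An opposite response in the RNAs of that slide is excluded, because the lowest list median on the other intercaruncular arrays of both was 1.669. Whether the ratio or the RNA labels were exchanged was not tested.

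The third pattern is the absence of an interferon response on both arrays of B98070 and of B4, labelled pregnant in intercaruncular tissue. Complete failure of hybridisation of slides 54, 64 and 65 is unlikely by the correlation of probes of one gene, in which the lowest of them ranked 5 of 18 arrays. Partial failure is not excluded, because the limit on that rank was chosen after the data were seen. Slide 54 also had the largest standard deviation of all arrays, 0.844, and correlated at 0.006 with the mean of the other arrays of its area. Slide 53 ranked 2, and its failure cannot be told apart, because slide 56 at the next rank did respond. A response in the cyclic partner RNAs is excluded, because the partners' other arrays had list medians of at least 1.757. RNA labelled pregnant that carries no response, from a cow without a conceptus or by exchange, cannot be told apart from what else remains, because the highest list median of the 4 arrays, 0.043, restates the pattern. B4 and B98070 also differed. B4 is labelled cyclic on caruncular slides 81 and 82. Its slides 64 and 65 correlated at 0.30 and 0.21 with the mean of the other arrays, against -0.016 and 0.006 for slides 53 and 54. OXTR was -1.20 and -1.33 on the slides of B4, and -0.09 and -0.84 on those of B98070.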

How the results depend on the processing

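Alternatives said here to be added were chosen after the data were seen. The intercaruncular count of 1452 stayed within 1.5 times under independent arrays (1569), no channel term (1359), the loop as a block (1948), loop 2 alone (2121), centring (1444), scaling (1603), values on all 18 arrays (1432), probes on their own (1375), robust moderation with trend (1186), no animal B4 (1206), the unmoderated test (1068) and, added, slide 49 turned (1709), the position trend removed (1295), no slides 51 and 53 (1423) and a dye term in place of channel order (1439). It was 489 at adjusted p under 0.01, 365 with a fold of at least 1.5, and 0 with one level per RNA, with loop 1 alone and with signs by dye. The cause was not tested. In simulated data one level per RNA recovered 55.2% of features changed by 0.5, 76.1% at 1 and 97% at 2, at 0% false calls. Those data gave every array the same effect, unlike the real arrays. Loop 1 has 10 arrays against 8 in loop 2. Array weights, an added alternative, gave 3416, and the cause was not tested. With the dye term, loop 1 alone gave 0 and loop 2 alone 1969. Leaving out each slide and each RNA in turn, also added, gave between 556 and 2040. The count fell below 1452 by over 1.5 times without slide 60 (876) or slide 66 (947), and without the RNA of pregnant B3 (557), B2 (587) or B6 (750) or of cyclic B7 (556), B5 (773) or B808 (893). All of these lie in loop 2 of the area, and each of these fits also has fewer arrays.

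The caruncular count of 4 became 0 with one level per RNA, without the channel term, in loop 2 alone, with robust moderation with trend, without animal B4, with signs by dye, with the unmoderated test and at adjusted p under 0.01. It was 7 with scaled arrays, 340 at adjusted p under 0.08, 2 with a fold of at least 1.5, 1041 in loop 1 alone and 1543 with the loop as a block. Added alternatives gave 2 with the position trend removed, 14 with array weights, 341 with loop 2 signed by channel order, 922 with that sign turned, 1795 with the loop as a block and the trend removed, and, with a dye term in place of channel order, 0 over the area, 417 in loop 1 alone and 0 in loop 2 alone. The dye term rests on 1 array with the pregnant RNA in Cy5 in loop 1. Leaving out each slide and RNA in turn gave 0 to 14. It gave 0 without slide 67, 68, 69, 71, 72, 73, 74, 77 or 81, 1 without slide 78, 79, 80 or 82, 2 without slide 70 or 83, and 14 without slide 75. It gave 0 without the RNA of pregnant B98114, B98095, B98104, B9098, B3, B714 or B2 or of cyclic B9090, B9115, B9105, B9114, B4 or B857, 1 without pregnant B1 or cyclic B5 or B808, 13 without cyclic B7 and 14 without pregnant B732. The cause was not tested, beyond the difference between loops. The difference between areas (50) became 0 with one level per RNA, in loop 1 alone, without animal B4 and at adjusted p under 0.01. It was 4 with scaled arrays, 133 at adjusted p under 0.08, 2301 in loop 2 alone and 153 with slide 49 turned (added). The cause was not tested. The loop difference of 48 in intercaruncular tissue was 24 with the position trend removed, and the cause was not tested. The correlation between areas was 0.078 in loop 2 alone. The count of lists past the threshold fell to 0 with an estimated correlation in each comparison, while fry gave 9 in intercaruncular tissue, 6 in caruncular tissue and 0 for the difference. Caruncular loop 2 alone gave 4 lists.

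Directions of lists turned under loops alone, an added alternative. Oxidative phosphorylation turned in intercaruncular loop 1 (adjusted p = 0.179) and in caruncular loop 2 (0.268), and trophoblast markers turned in caruncular loop 2 (0.704). For the difference between areas in loop 1 alone, the turned lists were interferon-stimulated genes (1.66e-12), MHC class I (2.30e-05), MHC class II (0.784), complement (0.179) and extracellular matrix (5.33e-04). Signs by dye turned 58 named intercaruncular genes, none of which passed that fit. In intercaruncular loop 2 and caruncular loop 1 the correlations of arrays that share an RNA argue against the dye rule. The fit by dye has 1 common sign for both areas, so these genes turned together by that choice. With the other common sign they would keep their direction, and the caruncular genes would turn. Their values, in log2, were RSAD2 -0.476, ISG15 -0.362, MX1 -0.264, MX2 -0.426, SCARA5 -0.192, DKK1 -0.149, HPGD -0.452, LOC282255 -0.037, FABP3 -0.056, C1R -0.107, ZNFX1 -0.168, OXTR 0.443, COL1A2 0.204, SPARC 0.138, CCN3 0.021, NPY 0.468, SNAI2 0.337, PMEPA1 0.310, COL1A1 0.304, PRXL2A 0.550, MFAP5 0.063, PGR 0.096, EPSTI1 -0.008, PARP9 -0.133, PSMB9 -0.137, BOLA-DRA -0.079, C1S -0.024, C4A -0.082, NKG7 -0.021, TPM1 0.012, TAGLN 0.128, CCND3 -0.104, PCNA 0.060, FBLN5 0.040, NDUFB5 0.041, NDUFA5 0.084, DNAJB11 0.158, PDIA6 0.127, CXCR4 -0.048, CCL8 -0.095, PECAM1 0.048, CLDN3 -0.052, PTGDS -0.073, CTSH -0.040, PLAU 0.078, LGALS1 0.079, CD44 0.092, IGF2 -0.119, AXIN1 -0.046, SLC2A1 -0.092, LDHB 0.086, LDHA 0.167, SLC27A6 -0.152, RPL27 0.025, RPS14 -0.016, DUSP1 -0.035, GADD45B -0.166, ZFP36 -0.085. Among genes named by rule or after their values were seen, a change of sign where neither setting passed was seen in caruncular tissue for 13 in loop 2 alone (among them PGR, IGFBP5, LDHA, CXCR4 and GADD45G), 13 there with the dye term, 7 with loop 2 signed by channel order, 2 in loop 1 alone and 1 there with the dye term. In intercaruncular tissue it was seen for 8 with signs by dye and for 1 each with array weights, in loop 2 alone and in each loop alone with the dye term. For lists it was seen in 13 caruncular, 12 intercaruncular and 5 difference pairs of a list and an alternative. The restriction to animals of only 1 area could not be run. Background intensities were not used here, so what signal over background limits was not assessed.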

Other observations

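All values in this part concern genes and lists named by rule or chosen from the lists fixed in advance, and the loop values were added after the data were seen.

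In intercaruncular tissue the glucose transporter SLC2A1 was higher at 1.47 (SE 0.27, n = 18 arrays, above 0 on 16), while LDHA and LDHB, subunits of lactate dehydrogenase, were lower at -0.99 (SE 0.22) and -0.36 (SE 0.08). Of 20 glycolysis genes 1 was higher and 2 lower, and as many adjusted over the list alone. TIMP2, an inhibitor of matrix proteases, had 1.08 (SE 0.18) and PLAU, the urokinase protease, -0.75 (SE 0.17). Of 31 proteases and inhibitors 3 were higher and 4 lower, and 5 and 8 adjusted over the list alone. The chemokine receptor CXCR4 had 0.98 (SE 0.22), CXCL10 0.70 (SE 0.18) and CCL8 0.59 (SE 0.17), the 3 higher genes of 27 in their list, with 4 higher and 4 lower adjusted over the list alone. Of 23 adhesion genes 1 was higher and 5 lower, and 6 and 7 adjusted over the list alone, with the galectins LGALS1 at -0.60 (SE 0.12) and LGALS3 at -0.62 (SE 0.13). That list had a median of 0.02 and a mean of -0.01, and its test pointed down. Median, mean and test also differed in sign for the chemokine and erythroid lists. IGF2, a growth factor, had 0.62 (SE 0.15), the 1 gene past the threshold of 12 in the insulin-like growth factor list (4 higher and 3 lower adjusted over the list alone).

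Of 20 solute transporters 4 were higher and 2 lower (6 and 2 adjusted over the list alone), among them the fatty acid transporter SLC27A6 at 0.87 (SE 0.22). Of 33 genes of cholesterol and fatty acid metabolism 3 were higher and 1 lower (4 and 4), the elongase ELOVL5 at -0.55 (SE 0.09). Of 20 prostaglandin genes 2 were higher (3), HPGD and PTGDS (0.85, SE 0.27). Of 23 genes of the steroid list 4 were higher and 3 lower (6 and 7). Of 19 WNT genes 2 were higher and 2 lower (2 and 2), with DKK3 at -0.66 (SE 0.15). Of 19 epithelial markers 2 were higher (2), the claudins CLDN3 at 0.62 (SE 0.18) and CLDN7 at 0.32 (SE 0.09). Of 17 endothelial markers 1 was higher and 2 lower (1 and 2), and of 55 ribosomal proteins 3 were higher and 6 lower (3 and 6). Of 24 heat shock and immediate early genes 3 were higher (5 higher and 1 lower), DUSP1 at 0.56 (SE 0.12). Numbers in parentheses without SE are adjusted over the list alone. By limma no gene passed among 18 macrophage, 8 B cell, 5 erythroid and 18 trophoblast markers, nor adjusted over the list alone. None of these 18 lists passed camera, with adjusted p from 0.0837 to 0.878, and by fry prostaglandin genes (0.0221) and solute transporters (0.0494) passed.

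In caruncular tissue 21 lists did not pass, with adjusted p from 0.0757 for complement to 0.972, and none of their genes passed over all genes tested. Adjusted over the list alone, complement had 4 higher and 1 lower, heat shock genes 4 and 1, cholesterol and fatty acid genes 4 and 1, proteases 4 and 5, glycolysis 3 and 3, the steroid list 3 and 1, chaperones 2 and 3, chemokines 2 and 3, prostaglandin genes 2 and 1, endothelial markers 1 and 3, WNT genes 1 and 2, and MHC class II 2, epithelial markers 1, adhesion 2 lower and growth factor genes 2 lower. T and NK, macrophage, B cell, erythroid, cell cycle and transporter lists had 0. For B cell, macrophage, erythroid, prostaglandin and transporter lists the median, mean and test differed in sign. SERPINA14, a serpin of the uterine glands, had 1.30 (SE 0.32, adjusted p = 0.0771) over 18 arrays and 2.81 (SE 0.17) in loop 1, where it passed by limma (adjusted p = 4.02e-05). IGFBP5 had -1.83 (SE 0.38) and PAG17 0.94 (SE 0.22) in loop 1, both past the threshold there, and 0.04 each in loop 2. With a dye term in place of channel order PAG17 did not pass in loop 1.

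On slides 64 and 65, of animal B4, OXTR had -1.20 and -1.33 although the interferon list medians were -0.19 and 0.04. These arrays correlated at 0.30 and 0.21 across features with the mean of the other arrays of the area.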
